A study of Mus musculus with 2 samples.

How the data were processed

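The series holds 2 single-cell libraries from mouse lung, titled as niche cells and distal lung cells and both given as CD45-negative, taken 7 days after intravenous injection of Labelling-4T1 cells. Per the labels' protocols, libraries were made with the Chromium Single Cell 3' chemistry, which counts molecules by UMI at the 3' end of transcripts, and sequenced on an Illumina HiSeq with a target of 50000 reads per cell. Per the submitters' processing notes, Cell Ranger 2.1.1, R 3.4.1 and the mm10 genome were used. The files hold raw UMI counts per gene and cell, 1 table per library, as deposited by the authors, with no normalization in the values. The labels do not say how niche cells were separated from distal cells or whether injected cells were gated out.

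The tables held 1473 niche and 1996 distal barcodes with 5283584 and 4791701 UMIs. Each table lists its own genes: 10791 in the niche and 10814 in the distal table, of which 10198 are in both. The lowest total of a listed gene was 10 UMIs in the niche and 12 in the distal table, so a gene missing from a table is not a count of 0, and no ratio was given for it. Ratios were scaled to the UMIs of the 10198 common genes. UMIs per barcode ran from 1245 to 9784 in the niche and from 685 to 7051 in the distal table, so the tables had different lower limits of depth.

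Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which left out 50 niche and 9 distal barcodes, all for few genes. Counts were scaled to 10000 per cell and logged, 2000 variable genes and 20 principal components were taken, and a graph of 15 neighbours was clustered with the Leiden method at resolution 1 (Python 3.11.15, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3). The 18 clusters were named from 25 fixed marker lists as "like" a cell type, with at least 3 markers detected in 25% of cells. No cluster was left unnamed. A mesenchymal-like cluster led by chemokine and stress genes and an endothelial-like cluster led by Ido1 and Ubd kept their class by markers further down. Doublets were called with Scrublet in each library (12 niche and 27 distal cells) and kept, with their removal as an alternative.

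UMIs were summed per library over all cells and over each class with at least 20 cells in both libraries. The log2 ratio of niche over distal used sums scaled to the class total with 0.5 UMI added to each, and its interval is the exact 95% conditional binomial interval without that addition. Against a sum of 0 a fold was computed with 3 UMIs over the class in place of the 0. It leaves out the error of the other sum and is not a 95% bound. Shares of cells have exact Clopper-Pearson 95% intervals. The cell cycle share was taken after thinning each cell to 1200 UMIs, the 20th percentile of the distal library rounded down to a multiple of 100. With 1 library per group, no p-value, standard error or count of changed genes was computed, and cells were not treated as replicates.

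The gene lists, marker lists, filters, rule for named genes and main alternatives were fixed before the data were examined. The 20 lists are alveolar type 2, alveolar type 1, epithelial progenitor, transitional alveolar cell, cell cycle, interferon response, MHC class I, MHC class II, acute phase and NF-kB, glycolysis and hypoxia, respiratory chain, lipid synthesis, extracellular matrix, sprouting endothelial, mature endothelial, Wnt pathway, epithelial to mesenchymal transition, immediate early and dissociation, endoplasmic reticulum stress, and antioxidant genes. A member was measured with 10 UMIs over both libraries, and a list needed 5 measured members. Each median has a 95% range over 1000 Poisson redraws and a percentile among 10000 random lists matched on expression, as a description of these libraries. Named genes were the 12 highest and 12 lowest by the interval bound nearest 0 among genes with 30 UMIs, without mitochondrial, ribosomal, haemoglobin and unnamed genes, plus list members with the largest bounds (not all of these genes are reported here) and Ly6a, Tm4sf1, Cd24a, Epcam, Sftpc, Ptprc, Pecam1 and Pdgfra. The alveolar type 2-like set, the mixed epithelial cluster as a set, the Malat1 limit, Xist, the use of Nkx2-1 and the naming of genes listed in 1 table only were chosen after their values were seen. Members at 0 in 1 library were also set to 3 UMIs. This moved the medians of alveolar type 2 genes in endothelial-like cells from -2.21 to -2.04, of mature endothelial genes in epithelial-like cells from -1.30 to -1.24, and of some lists in the alveolar type 2-like set, by at most 1.92 (sprouting endothelial genes).

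The steps were tested on simulated counts drawn from the summed UMIs, with 100 genes at 2-fold and 100 at 4-fold in each class. In mesenchymal-like cells (8684 genes), 96.0% of intervals held the true value at 2-fold and 97.0% at 4-fold. They excluded equality for 75.0% of 2-fold and 99.0% of 4-fold changes, against 3.74% of unchanged genes. In endothelial-like cells (8569 genes) the shares excluding equality were 86.0% and 100% and in epithelial-like cells (4763 genes) 73.0% and 98.0%. Lists of 20 genes at 2-fold had a median log2 ratio of 0.96, 0.99 and 1.00 in the mesenchymal-like, endothelial-like and epithelial-like simulations. Cells redrawn from the profile of their cluster were given back their class in 100% of epithelial-like, endothelial-like, mesenchymal-like and immune-like cells. All these draws held counting error only, without variation between cells of a cluster, free RNA or doublets. They check the computation and do not show how the steps behave on real cells.

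The alternatives were other limits on genes and mitochondrial share, no filter, doublets left out, resolutions 0.5 and 2, 10 components, each library clustered alone, classes from marker sums, other scalings, thinning, other minimum counts for list members, and leaving out immune-like cells. Another 9 were added after the data had been seen. Gene positions were matched by Ensembl identifier for 167 of 167 named genes. Close paralogues, such as Lyz1 and Lyz2, Gbp2 and Gbp2b, or the Ccl21 genes, were taken as assigned upstream, so their separate values are less certain.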

Results

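Single-cell RNA sequencing was available for 2 libraries of mouse lung cells that lacked the pan-leukocyte surface protein CD45, collected 7 days after intravenous injection of Labelling-4T1 cells. 4T1 is a mouse mammary carcinoma line that seeds the lung, and the labelling version passes a fluorescent protein to the cells around it. One library held niche cells and 1 held distal lung cells, so every comparison below rests on 1 library per group. The niche library held 1423 cells after filtering, with 5139368 transcript molecules (unique molecular identifiers, UMIs) and a median of 2975 UMIs and 1349 genes per cell. The distal lung library held 1987 cells, with 4781222 UMIs and a median of 1975 UMIs and 1074 genes per cell. No difference had a replicate check, no test between groups was possible, and all intervals cover counting error only. The comparisons address which non-immune cells were present near the tumour cells and how their transcripts differed from those of cells farther away.

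Mesenchymal-like cells, named by fibroblast and pericyte markers, made up 54.9% of the niche library (781 of 1423 cells, exact binomial 95% interval 52.3% to 57.5%) and 20.03% of the distal library (398 of 1987, 18.3% to 21.9%). Endothelial-like cells made up 34.9% of the niche library (496 cells, 32.4% to 37.4%) and 65.8% of the distal library (1308 cells, 63.7% to 67.9%). Epithelial-like cells made up 6.75% of the niche library (96 cells, 5.50% to 8.18%) and 12.8% of the distal library (255 cells, 11.4% to 14.4%). The alveolar type 2-like cells among them, which carry surfactant transcripts, numbered 17 in the niche library and 215 in the distal library, and the alveolar type 1-like cells 8 and 28. Another epithelial cluster, led by Scgb1a1, Sfn, Krt18 and Krt8 and of no named subtype, held 71 niche and 12 distal cells and is called the mixed epithelial cluster. Immune-like cells were 3.51% (50 cells) of the niche and 1.31% (26 cells) of the distal library. No cluster of kept cells was named mesothelial-like, erythroid-like, platelet-like or glial-like, which sets no limit on single cells of these types. These shares can be set by the sort, by dissociation and by the depth difference between the libraries. With at least 1000 genes required per cell, the epithelial-like share of the distal library was 20.7%. Of the 96 niche epithelial-like cells, 58 had little of the nuclear RNA Malat1. The origin of 54 of these, in the mixed epithelial cluster, is open. Without all low-Malat1 cells the niche share was 3.05%.

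**Figure D1:**
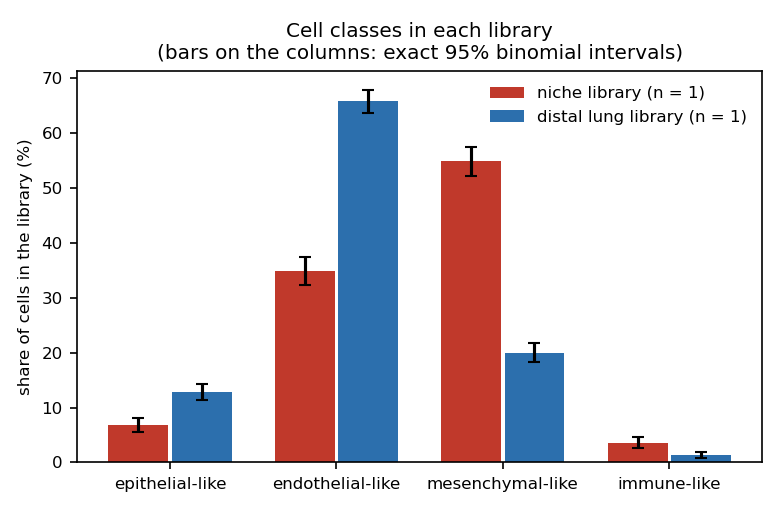
Share of cells (%, vertical axis, from 0) in 4 classes in the niche library (red) and the distal lung library (blue), 1 library each. Lines on the columns are exact 95% binomial intervals. Mesenchymal-like cells were 54.9% of the niche and 20.03% of the distal library, and endothelial-like cells 34.9% and 65.8%.

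Over all cells, the single genes with the highest niche to distal ratios included chemokine, matrix and acute phase genes, and those with the lowest included genes of alveolar type 2 cells. Timp1, an inhibitor of matrix metalloproteinases, had a log2 ratio of 5.16 (95% interval 4.88 to 5.46; 4031 against 105 UMIs). The chemokine genes Cxcl9 (log2 ratio 5.01, 4.78 to 5.25), Ccl7 (4.94, 4.66 to 5.25), Cxcl10 (4.49, 4.38 to 4.61) and Ccl2 (4.32, 4.16 to 4.49) followed. The same end held the matrix gene Tnc (4.38), complement factor gene Cfb (3.67), Serpina3n (3.50), Tnfaip6 (3.30), the galectin gene Lgals1 (3.28) and the metallothionein gene Mt2 (3.12). The club cell secretory gene Scgb1a1 (3.25) rested on 4 cells with 13996 of its 17569 niche UMIs, and its ratio was 0.77 with at least 1000 genes required per cell. At the other end stood Lyz1 (log2 ratio -5.47, -5.64 to -5.30), the calcium-binding protein gene S100g (-5.12) and the surfactant genes Sftpc (-3.97, -3.99 to -3.94), Sftpa1 (-3.89) and Sftpb (-3.89). Pla2g1b (-4.16), Sfta2 (-3.77), Lyz2 (-3.70), Ppp1r14c (-3.67), the phosphate transporter gene Slc34a2 (-3.65), Napsa (-3.54) and Cxcl15 (-3.37) lay beside them.

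A member of a gene list was counted as 2-fold higher or lower where its ratio reached 2-fold and its counting interval excluded equality. Over all cells, 27 of 31 measured extracellular matrix genes were 2-fold higher in the niche and 0 were 2-fold lower (median log2 ratio 1.73, 95% range of Poisson redraws 1.60 to 1.83). This was in the direction of the class shares: mesenchymal-like cells held 3196401 of 5099569 niche and 924091 of 4758695 distal UMIs, and the median within them was 0.52. Interferon response genes had a median of 1.04 (0.98 to 1.20), with 13 of 26 members 2-fold higher, among them Zbp1 (2.16) and Rsad2 (2.25). Of 18 acute phase and NF-kB genes, 8 were 2-fold higher (median 0.79), with the cytokine gene Il6 at 2.87 and the complement gene C3 at 2.60. All 14 alveolar type 2 genes (median -3.31), 15 of 19 mature endothelial genes (-1.19) and 6 of 8 alveolar type 1 genes (-1.38) were 2-fold lower, in the direction of the class shares. Ly6a, which encodes the surface protein Sca-1, had a log2 ratio of 0.39 (0.35 to 0.42), Tm4sf1 -1.17, Cd24a -0.75, Epcam -0.93, the endothelial gene Pecam1 -1.27 and the fibroblast gene Pdgfra 0.99. Ptprc, which encodes CD45, was listed only in the niche table, with 46 UMIs.

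**Figure D2:**
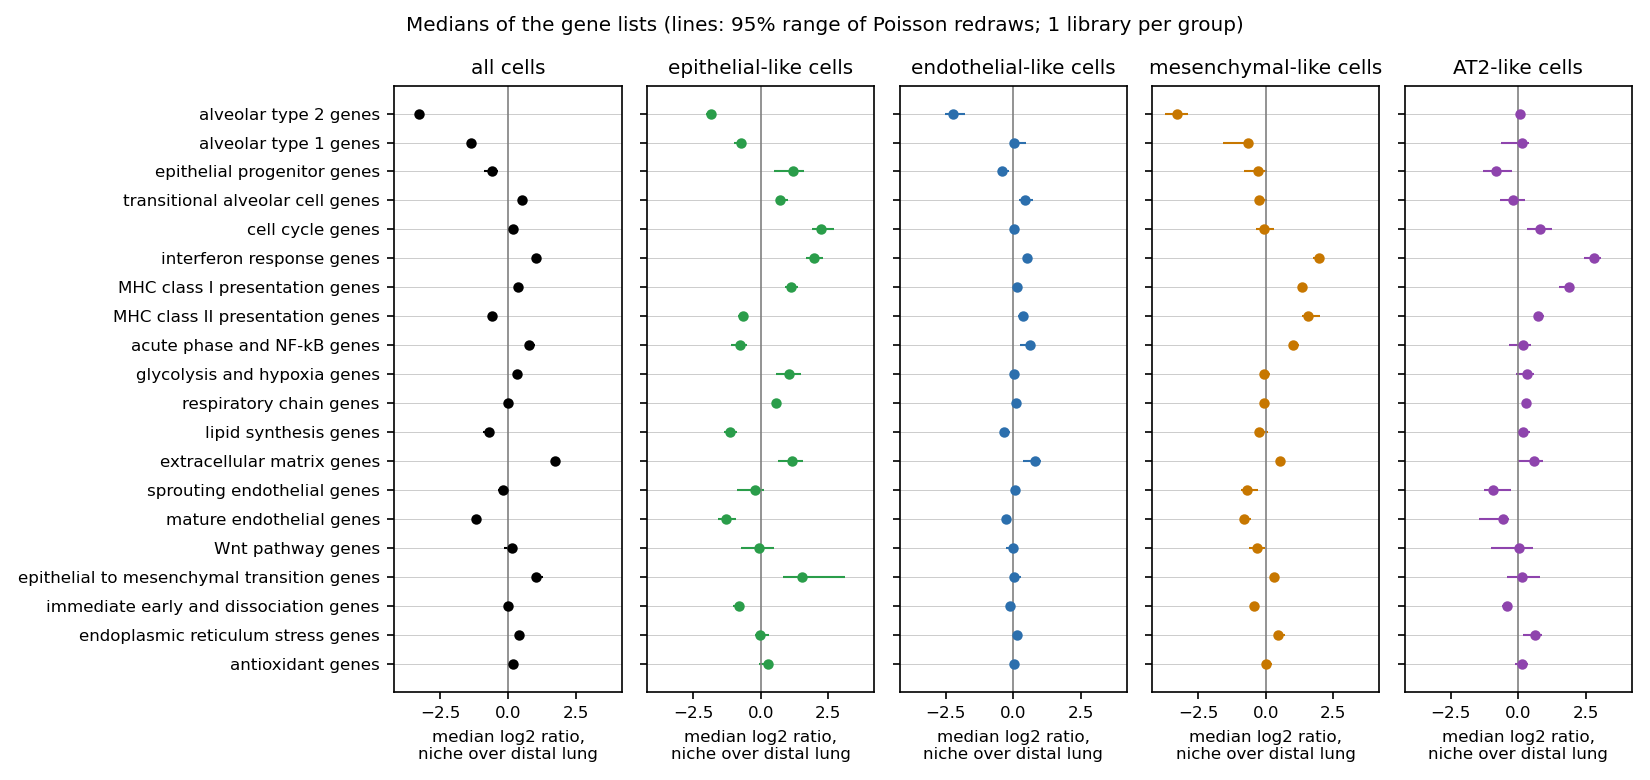
Median log2 ratio of niche over distal lung (horizontal axes) for 20 gene lists in all cells, in 3 classes and in alveolar type 2-like (AT2-like) cells. Lines are 95% ranges of Poisson redraws, 1 library per group. Interferon response genes had medians of 1.04, 1.99, 0.51, 1.97 and 2.79 in the panels from left to right.

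Mesenchymal-like cells of the niche carried more transcripts of interferon response, antigen presentation and acute phase genes than those of the distal library. Cxcl9, the gene of a chemokine induced by interferon gamma, had a log2 ratio of 6.19 (5.58 to 6.96; 4918 against 19 UMIs), and Cxcl10 one of 4.49 (4.28 to 4.72). The antiviral gene Rsad2 had 395 UMIs in the niche and 0 in the distal library, 38.1-fold higher with the 0 taken as 3 UMIs. The secreted factor gene Cytl1 had 223 and 0, 21.5-fold higher on the same terms. Ubd (6.12, 4.22 to 12.01; 361 against 1 UMI), Mlkl, a gene of necroptosis (4.49, 2.56 to 10.38; 116 against 1 UMI), the iron-binding lipocalin gene Lcn2 (4.15), Timp1 (3.84, 3.53 to 4.19), Serpina3g (3.78), Ccl21a (3.44), the guanylate-binding protein gene Gbp4 (3.29) and Ccl7 (3.28) were also among the highest. Of 26 interferon response genes, 22 were 2-fold higher and 0 were 2-fold lower (median log2 ratio 1.97, 1.73 to 2.17, percentile 100 among random lists). The same held for 13 of 15 MHC class I presentation genes (median 1.35), with the proteasome gene Psmb8 at 2.26 and the peptide transporter gene Tap1 at 2.36, and for 5 of 6 MHC class II presentation genes (median 1.57), with H2-Eb1 at 2.27 and Cd74 at 1.83. Acute phase and NF-kB genes had 9 of 18 members 2-fold higher (median 0.99), with Ccl2 at 2.66 and Cxcl2 at 2.32. Matrix genes had a median of 0.52 (0.41 to 0.61), with 6 of 31 members 2-fold higher, among them Timp1 and Tnc (3.07), while Postn had -0.58.

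Lower in niche mesenchymal-like cells were Tcf21, a transcription factor gene of lung lipofibroblasts (log2 ratio -2.00, -2.14 to -1.86), the water channel gene Aqp1 (-2.14) and Pdzd2 (-2.18). Mature and sprouting endothelial genes also had lower medians in these cells, -0.80 (-0.91 to -0.55) and -0.68 (-0.92 to -0.29). Free RNA of endothelial-like cells was not tested as a source of the Aqp1 ratio. For Tcf21, Pdzd2 and the matrix gene Postn, the mix of clusters in the class differed in the same direction. A cluster led by Slc7a10 and Tcf21 held 33.2% of distal and 9.35% of niche mesenchymal-like cells. The pericyte-like cluster, with Pdzd2 and Postn among its leading genes, held 8.54% and 2.69%. Pdgfra had a log2 ratio of -0.68 (-0.89 to -0.46) and Ly6a one of 1.94 (1.81 to 2.08). The alveolar genes Lyz1 (-5.01), Slc34a2 (-4.56), Sftpd (-4.17), Sftpc (-4.03), Cxcl15 (-3.57), Sftpa1 (-3.55), Sftpb (-3.51) and Ager (-2.74) and the sodium pump gene Atp1b1 (-3.10) were lower too. Sftpc stood at 122 CPM (counts of a gene scaled to a common total of UMIs) in niche and 2008 in distal mesenchymal-like cells. Ccl21a, high in niche mesenchymal-like cells, stood at 5910 CPM in niche and 898 in distal endothelial-like cells. Free RNA from endothelial-like cells was not tested as its source. Saa3, a serum amyloid gene, was listed only in the niche table, with 5743 UMIs in these cells. Of the niche cells of this class, 23.8% lay in a cluster led by Cxcl9, Timp1, Ccl2 and Cxcl10 themselves, so its size was not compared between the libraries. Of its 186 niche cells, 63 had little Malat1, against 108 among all 781 niche cells of the class. Without that cluster, the interferon median was 1.39 and the medians of MHC class I, MHC class II and acute phase genes were 1.06, 0.62 and 0.69, while Lcn2 had 0.90, Serpina3g 2.80 and Timp1 3.01. With cells thinned to 1 depth, Cxcl9 had 4.75, Cxcl10 3.66 and Tcf21 -1.31.

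**Figure D3:**
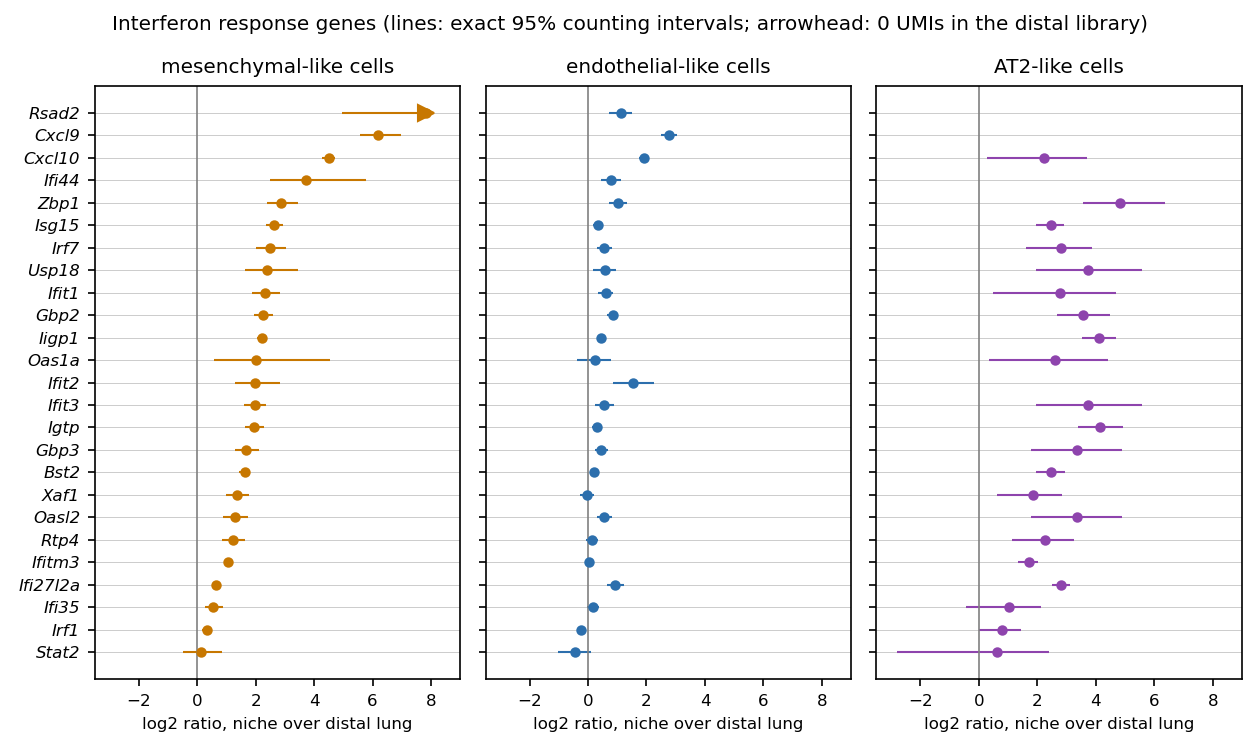
Log2 ratio of niche over distal lung (horizontal axes) for measured interferon response genes in mesenchymal-like, endothelial-like and alveolar type 2-like (AT2-like) cells. Lines are exact 95% counting intervals, and the arrowhead marks Rsad2, which had 0 UMIs in distal mesenchymal-like cells. Of all genes measured, not all of them shown, 22 of 26, 5 of 26 and 19 of 22 were 2-fold higher in the niche.

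In endothelial-like cells the genes with the highest ratios included chemokines and interferon-induced genes, while the interferon and MHC list medians were smaller than in mesenchymal-like cells, a difference that was not tested. Ubd, a ubiquitin-like modifier induced by interferon gamma, had a log2 ratio of 3.50 (3.19 to 3.83; 594 against 99 UMIs) and Cxcl9 one of 2.77 (2.51 to 3.06; 508 against 140 UMIs). Fcer1g (4.30), Ccl21a (2.72, 2.65 to 2.79) and the ion transport regulator gene Fxyd6 (2.63) were also high. These 3 genes lead a lymphatic-like cluster that held 34 niche and 11 distal cells, and without it their ratios were 1.81, 1.22 and 1.04. The cluster led by Ido1 and Ubd held 8.06% of niche and 1.99% of distal endothelial-like cells, a shift in the direction of the Ubd ratio. The bone morphogenetic protein gene Bmp2 (4.35, 3.05 to 6.44), Ccl2 (3.77), Mt2 (3.39), the transcription factor gene Maf (3.13), the placental growth factor gene Pgf (3.09), Lgals1 (2.79) and the complement inhibitor gene Serping1 (2.41) completed the highest genes. Of 26 interferon response genes, 5 were 2-fold higher, among them Cxcl10 (1.92), Ifit2 (1.54) and Zbp1 (1.03), and the median was 0.51 (0.37 to 0.57, percentile 100 among random lists). Extracellular matrix genes had 10 of 29 members 2-fold higher (median 0.80, 0.37 to 1.03), led by Col3a1 (1.91; 58 against 29 UMIs), and acute phase genes 6 of 17 (median 0.60). The matrix values rest on low counts beside free RNA: Col1a1 stood at 17.4 CPM in niche and 7.32 in distal endothelial-like cells, against 1647 and 1154 in mesenchymal-like cells, and a set of fibroblast genes had a median of 1.46% and 0.635% of the mesenchymal-like level. At these shares free RNA alone would give Ccl2 30.7 of its 44.5 CPM in the niche and 2.12 of its 3.09 CPM in the distal library, and Cxcl1 19.1 of 35.8 and 3.01 of 9.27, but Ubd only 1.65 of 434 and Cxcl9 22.5 of 371 CPM in the niche. MHC class II genes had a median of 0.35 and MHC class I genes 0.15, with 0 members 2-fold higher in either list. Over the alternatives, the median of acute phase genes lay between 0.12 and 0.86.

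Among genes lower in niche endothelial-like cells, the prostaglandin synthase gene Ptgs2 had a log2 ratio of -2.18 (-3.29 to -1.33; 11 against 98 UMIs). Mature endothelial genes had a median of -0.28 (-0.32 to -0.24), with Vwf, the gene of von Willebrand factor, at -1.33, the angiopoietin receptor gene Tek at -0.70 and Car4 at 0.53. The mix of clusters shifted the same way for Vwf and Car4: clusters with Vwf among their leading genes held 10.1% and 6.04% of distal and 5.85% and 3.43% of niche endothelial-like cells, and the cluster led by Ednrb and Car4 9.56% and 17.9%. Pecam1 had a log2 ratio of -0.30, Tm4sf1 -0.38, Cd24a 0.43 and Ly6a 0.63 (0.58 to 0.67). Of 24 sprouting endothelial genes, 5 were 2-fold higher, among them Pgf, Trp53i11 (1.16) and Angpt2 (1.15), and the median was 0.06 (-0.06 to 0.18). The other lowest genes were AU021092 (-2.53) and genes of alveolar or airway epithelium, namely Cbr2 (-4.29), Slc34a2 (-3.76), Lyz1 (-3.71), S100g (-2.51), Sftpc (-2.50), Cxcl15 (-2.41), Sftpa1 (-2.35), Ager (-2.24), Sftpd (-2.11) and Sftpb (-1.97). Sftpc stood at 341 CPM in niche and 1941 in distal endothelial-like cells, beside 140 and 1567 in immune-like cells, which should lack it, and 174932 and 227076 in alveolar type 2-like cells.

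Epithelial-like cells of the 2 libraries differed first in kind: the mixed epithelial cluster held 71 of 96 niche cells and the alveolar type 2-like cluster 215 of 255 distal cells. All 14 alveolar type 2 genes were 2-fold lower in the niche (median log2 ratio -1.84, -2.04 to -1.74), with Sftpc at -2.38, Sftpa1 at -2.31 and Sftpb at -2.32. Of 19 measured cell cycle genes, 18 were 2-fold higher (median 2.24, 1.89 to 2.72), among them the centromere gene Cenpa (5.68, 4.28 to 8.21; 62 against 3 UMIs) and the cyclin kinase subunit gene Cks1b (4.98). Lgals1 (8.42, 7.98 to 8.94; 4575 against 38 UMIs) and the intermediate filament gene Vim (5.16, 4.68 to 5.71) led the epithelial to mesenchymal transition list, in which 6 of 11 members were 2-fold higher (median 1.53). Interferon response genes had 20 of 26 members 2-fold higher (median 1.99, 1.68 to 2.31), with Cxcl9 at 6.95 (5.38 to 10.33; 107 against 2 UMIs), and MHC class I genes 7 of 14 (median 1.12). Glycolysis genes had 8 of 19 members 2-fold higher and 3 lower (median 1.04), with the enolase gene Eno1 at 3.50 and the hypoxia-induced gene Vegfa at -1.52. Epithelial progenitor genes had 5 of 11 higher and 2 lower (median 1.21), with Ly6a at 1.95 (1.75 to 2.16), Tm4sf1 at 1.69 and Id2 at -2.36. Cd24a had a ratio of 0.04 (-0.34 to 0.39) and Epcam 0.66.

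The other highest genes in epithelial-like cells included the cytokine gene Tslp (6.86, 4.90 to 12.76, from 60 against 1 UMI) and Cenpa. The urokinase gene Plau (5.51, 3.86 to 8.91, from 39 against 2 UMIs) and the serine synthesis gene Phgdh (4.82) were others. Ubd and Oaf had 39 and 35 niche UMIs and 0 distal UMIs, 37.4-fold and 33.6-fold higher with the 0 taken as 3 UMIs. Their exact intervals began at log2 ratios of 4.86 and 4.69. Scgb1a1 (4.99, 4.90 to 5.07) and Scgb3a1 (10.04, 8.50 to 13.41; 913 against 2 UMIs) rested on 4 cells, which held 13996 of the 14291 Scgb1a1 UMIs and 906 of the 913 Scgb3a1 UMIs of the niche class. With at least 1000 genes required per cell, the Scgb1a1 ratio was -0.50. The lowest genes besides the surfactants included Lyz1 (-3.91), S100g (-3.57), Cd36 (-2.68), Lyz2 (-2.65), Rnase4 (-2.61) and Ppp1r14c (-2.61). Pla2g1b (-2.60), the selenoprotein gene Sepp1 (-2.60) and Creb3l1 were also among them. Creb3l1 had 0 against 49 UMIs, 5.67-fold lower with the 0 taken as 3 UMIs. Lipid synthesis genes had 13 of 25 members 2-fold lower (median -1.12), and acute phase genes 6 of 16 (median -0.76). Without the mixed epithelial cluster, the medians were -0.06 for alveolar type 2 genes, 0.80 for cell cycle genes, 0.08 for progenitor genes, 0.02 for lipid synthesis genes, 0.36 for glycolysis genes, 0.78 for epithelial to mesenchymal transition genes and 2.24 for interferon response genes. Vim then had a ratio of -0.02, Phgdh -0.54, Plau 1.04, Tslp 3.37 (2.78 without low-Malat1 cells), Sftpc -0.54, Lyz1 -2.08, Cd36 -1.02, Tm4sf1 0.77, Lgals1 2.93, Cenpa 0.56 and Cks1b 1.44. With cells thinned to 1 depth, the median of the epithelial to mesenchymal transition genes was 0.20.

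The mixed epithelial cluster also stood apart in the nuclear RNA Malat1. In 54 of its 71 niche cells Malat1 made up under 0.5% of UMIs, with none of the 71 between 0.194% and 0.559%. The 4 cells rich in Scgb1a1 lie among these 54, which held 14087 of the 14291 Scgb1a1 UMIs of niche epithelial-like cells. Malat1 stood at 606 CPM in the 54 cells and 1932 in low-Malat1 niche mesenchymal-like cells. In 14 low-Malat1 alveolar type 2-like and type 1-like cells it stood at 3254 CPM. The groups compared below were thus not matched on its loss. These 54 cells held 4 UMIs of Xist, the RNA that silences an X chromosome, or 16.3 CPM (4.44 to 41.7), against 975 CPM (751 to 1246) in the other 19 low-Malat1 epithelial-like cells of both libraries and 622 CPM (541 to 713) in low-Malat1 niche mesenchymal-like cells. The lung lineage factor gene Nkx2-1 had 0 UMIs in the 54 cells (up to 15.01 CPM) and 17 UMIs in the 19 others. Of these 19, 10 were distal alveolar type 2-like cells, 4 niche alveolar type 1-like cells and 5 distal cells of the mixed epithelial cluster, which held 0 UMIs of Xist and 1 of Nkx2-1. The 17 niche cells of the cluster with more Malat1 held 64 UMIs of Xist and 11 of Nkx2-1. Over the whole libraries, 12.6% of niche cells (179 cells, 10.9% to 14.4%) and 2.67% of distal cells (53 cells, 2.004% to 3.47%) lay under 0.5% Malat1, and 130 niche and 106 distal cells lay between 0.25% and 1%.

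**Figure D4:**
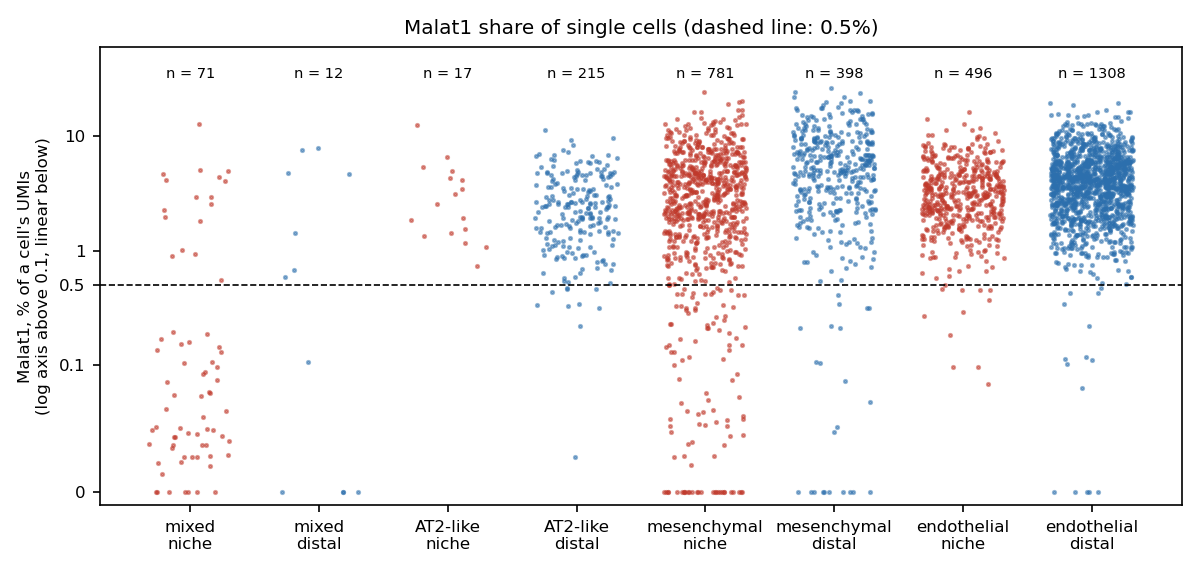
Malat1 share of each cell's UMIs (%, vertical axis, logarithmic above 0.1 and linear below) in the mixed epithelial cluster and in alveolar type 2-like (AT2-like), mesenchymal-like and endothelial-like cells of the niche (red) and distal lung (blue) libraries. Each point is 1 cell and the dashed line marks 0.5%. Of the mixed epithelial niche cells, 54 of 71 lie under the line.

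Alveolar type 2-like cells were compared as a set of their own, chosen after the data had been seen, and the 17 niche cells fall short of the 20 cells set as the minimum for a class. Their interferon response genes had a median log2 ratio of 2.79 (2.43 to 3.05), with 19 of 22 members 2-fold higher and 0 lower, and 13 of 14 MHC class I genes were 2-fold higher (median 1.87). The interferon-induced GTPase genes Iigp1 (4.10, 3.54 to 4.69; 68 against 45 UMIs) and Igtp (4.14), the guanylate-binding protein genes Gbp2b (4.14) and Gbp2 (3.58), AW112010 (3.31), Ifi47 (3.28) and Ifi27l2a (2.81) were among those with the highest ratios. The immunoproteasome genes Psmb9 (2.81) and Psmb8 (2.60), Itih4 (2.79) and Ly6a (2.50, 2.21 to 2.78; 155 against 314 UMIs) followed. MHC class II genes had a median of 0.71, with 1 of 6 members 2-fold higher. Lyz1 (-1.93, -2.12 to -1.76), S100g (-1.60), Ces1d (-1.67), Cbr2 (-1.18), Lyz2 (-0.69), Sepp1 (-1.27) and Mettl7a1 (-1.22) were lower, as were Ccnl1 (-3.01, -8.90 to -1.08), Id3 (-1.94), Rhob (-1.90 from 4 niche UMIs, -0.30 with cells thinned), Ptprb (-1.76) and the immediate early gene Ier2 (-1.15). Ptprb is among the fixed markers of capillary endothelial cells. Mature endothelial genes had a median of -0.57 (-1.47 to -0.35) in this set, with 4 of 19 members 2-fold lower. With members at 0 set to 3 UMIs that median was -0.23. Free RNA of endothelial-like cells was not tested as a source of the Ptprb ratio. Sftpc had a ratio of -0.39 (-0.41 to -0.37), Epcam -0.03 (-0.85 to 0.63) and Cd24a -0.82 (-2.05 to 0.06). Epithelial progenitor genes, the list that holds Ly6a, had a median of -0.82 (-1.31 to -0.23), with 2 of 9 members 2-fold higher and 2 lower. Over the alternatives this median lay between -1.06 and -0.08. Tm4sf1 had 1 UMI in the 17 niche cells and 42 in the 215 distal cells. This is 10.5 CPM (0.266 to 58.6) and 38.3 CPM (27.6 to 51.8), with intervals that overlap. Over the alternatives its log2 ratio lay between -2.47 and -0.03.

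Cells with at least 3 UMIs of cell cycle genes, counted after each cell had been thinned to 1200 UMIs, made up 59.4% of niche epithelial-like cells (57 of 96, 48.9% to 69.3%) and 16.8% of distal ones (42 of 250, 12.4% to 22.0%). The shares were 47.0% and 45.9% of endothelial-like cells, 28.2% (25.04% to 31.5%) and 21.9% (17.7% to 26.6%) of mesenchymal-like cells, and 37.0% and 36.4% of all cells. Thinning left out 347 distal cells and 0 niche cells as too shallow. The count used the 19 of 38 list genes found in both libraries' gene lists. Another 14 members, among them Birc5 and Ube2c, were listed for the niche only and were not counted. The shares are therefore not shares of dividing cells. Unthinned, the shares of all cells were 77.4% in the niche and 63.6% in the distal library. Without the mixed epithelial cluster, 20% of niche epithelial-like cells reached 3 UMIs.

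The remaining lists differed less or by class. Immediate early and dissociation genes, which respond to tissue handling, had medians of -0.82 in epithelial-like (0.10 without low-Malat1 cells), -0.11 in endothelial-like, -0.45 in mesenchymal-like and 0.01 in all cells, with Egr1 at -1.41 and Jun at -1.32 in epithelial-like cells. Endoplasmic reticulum stress genes had medians of 0.45 (0.36 to 0.73) in mesenchymal-like cells, with the chaperone gene Hspa5 at 0.80 and Sdf2l1 at 1.22, and of 0.15 in endothelial-like cells. Transitional alveolar cell genes had medians of 0.72 in epithelial-like cells (percentile 89.8 among random lists, whose median was 0.36), -0.19 in alveolar type 2-like and 0.44 in endothelial-like cells. Clu had 1.86 in epithelial-like cells, and Sfn, a leading gene of the mixed epithelial cluster, 3.39. Over the alternatives, the transitional medians lay between 0.26 and 1.32 in epithelial-like and between 0.13 and 0.67 in endothelial-like cells. Wnt pathway genes had medians of -0.33 in mesenchymal-like cells, with Sfrp1 at 1.70 and Nkd1 at -1.33, and of -0.02 in endothelial-like cells. Antioxidant genes had medians of 0.02, 0.04 and 0.26 in mesenchymal-like, endothelial-like and epithelial-like cells. The last lay at percentile 43.8 among random lists, whose median was 0.31. In mesenchymal-like cells the superoxide dismutase gene Sod2 had 2.17 and the glutathione transferase gene Gstm1 -1.34. Respiratory chain genes had medians of -0.05, 0.09 and 0.58 in the same 3 classes, the last at percentile 52.9 among random lists, whose median in epithelial-like cells was 0.57.

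The genes named most often lie, in the GENCODE annotation of mm10, on chromosome 5 from 92321347 to 92328079 (Cxcl9, ENSMUSG00000029417), on chromosome 5 from 92346638 to 92348889 (Cxcl10, ENSMUSG00000034855) and on chromosome X from 20870166 to 20874735 (Timp1, ENSMUSG00000001131). Ly6a (ENSMUSG00000075602) lies on chromosome 15 from 74994877 to 74998031, Lgals1 (ENSMUSG00000068220) on chromosome 15 from 78926725 to 78930465, and Sftpc (ENSMUSG00000022097) on chromosome 14 from 70520949 to 70524081. All are protein-coding genes.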

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

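In this part, the tests of free RNA, of barcodes with little Malat1, of the low-Malat1 epithelial-like cells and of the difference between the libraries were chosen only after the data had been seen, while thinning to 1 depth was planned.

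Immune-like cells appeared although both libraries were collected as CD45-negative: they made up 3.51% of niche cells and 1.31% of distal cells. Of the niche barcodes left out for few genes, 33 held mostly haemoglobin UMIs and 13 mostly Scgb1a1 UMIs (1 in the distal library). Saa3, whose gene is listed in the niche table only, reached 1797 CPM in niche mesenchymal-like cells. Some lists had medians of opposite sign in 2 classes, a difference that was not tested. Epithelial progenitor genes had medians of 1.21 in epithelial-like and -0.41 in endothelial-like cells. MHC class II genes had medians of -0.64 in epithelial-like, 0.35 in endothelial-like and 1.57 in mesenchymal-like cells. Acute phase genes had medians of -0.76 in epithelial-like, 0.60 in endothelial-like and 0.99 in mesenchymal-like cells. Without the mixed epithelial cluster the epithelial-like medians of the same 3 lists were 0.08, 0.57 and -0.00.

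Interferon response genes had higher medians in the niche in endothelial-like, mesenchymal-like and alveolar type 2-like cells. Free RNA from mesenchymal-like cells, taken off at the leaked share of their level, left medians of 0.48 (0.34 to 0.54) in endothelial-like and 2.79 (2.38 to 3.05) in alveolar type 2-like cells, which argues against it as the whole cause. With all cells thinned to 1 depth the lowest of the 3 medians was 0.42, which argues against depth. Without barcodes of little Malat1, which were 108 of 781 niche mesenchymal-like cells, the mesenchymal-like median was 1.87. This argues against such barcodes as the whole cause in that class. The endothelial-like median was then 0.50 and the alveolar type 2-like one 2.72. Only 11 of 496 and 0 of 17 niche cells of these sets were such barcodes, so their removal tests little there. A difference between the libraries other than the niche stays open and cannot be told apart from it, because each group has 1 library. A response of lung cells to the tumour niche is therefore a hypothesis that these data may fit but not test. More than 1 library per group would be needed to test it.

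The 54 niche cells of the mixed epithelial cluster with little Malat1 form the second pattern. The 4 cells rich in Scgb1a1 lie among them, so the 54 need not be of 1 kind, and they were tested as a set. Little Malat1 did not bring such a cell cycle share in another class. Of the 54, 87.0% (47 of 54, 75.1% to 94.6%) had 3 cell cycle UMIs after thinning. Among low-Malat1 mesenchymal-like niche cells the share was 29.6% (32 of 108, 21.2% to 39.2%). Malat1 stood at 606 CPM in the 54 cells and 1932 in the mesenchymal-like ones, and Neat1 at 4.07 and 80.4. The groups were thus not matched, and the comparison cannot decide for a deeper loss of nuclear RNA. The same limit holds for Xist. Lung epithelial cells short of nuclear RNA, with alveolar levels of Nkx2-1, are argued against for the 54 as a set by its 0 UMIs (up to 3.69). The level of 14 low-Malat1 alveolar type 2-like and type 1-like cells would give 65.6 (37.5 at its lower bound). That of all 19 other low-Malat1 epithelial-like cells would give 63.7 (37.1). The 14 cells held Malat1 at 3254 CPM, so they were not matched on its loss either. Of the same cluster, the 17 niche cells with more Malat1 would give 45.3 (22.6) and the 5 distal low-Malat1 cells 43.2 (1.09), the latter too few to decide, and the 19 others would give 240 UMIs of Xist (185) against 4 seen; an epithelial kind without these transcripts was not tested. Carcinoma cells of the injected line remain a candidate source that was not settled, with no gate against them in the labels. Of 16 carcinoma candidate genes listed, 6 were measured. Fosl1 (17 UMIs) and Krt14 (42 UMIs), 2 of these 6, were 2-fold above both other niche epithelial-like and low-Malat1 mesenchymal-like cells. Spp1 (log2 ratio 2.70) and Plaur (1.63) were 2-fold above the other niche epithelial-like cells only. Against the mesenchymal-like cells they had -1.37 and 0.52, and 9 of those 108 cells held all 185 Spp1 UMIs. Lcn2 (-4.79 and -3.93) and Areg (-3.73 and -1.75) were below both.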

How the results depend on the processing

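Some settings in this part leave out low-Malat1 cells or single clusters, or keep cells within both libraries' UMI limits. These were chosen only after the data had been seen. The other alternatives whose changed values are given below were planned. The counts over all alternatives also hold further settings, of which not all were planned. No paired analysis was possible because each group has 1 library. Over all alternatives, 65 class shares stayed within their interval and 7 moved. For the lists answering a comparison, 117 medians stayed within their redraw range and 15 moved, all in the same direction. Of other lists 1586 stayed and 146 moved, and of named genes 2070 stayed and 295 moved. Sign changes numbered 92 for lists and 16 for genes, of which 11 and 5 concerned values whose reported range excluded 0; these are given below. The cause was not tested unless the setting itself removes the cells concerned.

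With no filter, Scgb1a1 had a log2 ratio of -0.54 in epithelial-like cells. With at least 1000 genes, the distal shares were 20.7% epithelial-like and 58.8% endothelial-like, and the ratios were -1.65 for alveolar type 2 genes and -0.50 for Scgb1a1 in epithelial-like cells and 0.37 for interferon genes in endothelial-like cells. With doublets left out, interferon genes in epithelial-like cells had 2.36. Each library clustered alone gave a distal endothelial-like share of 62.0%. Classes from marker sums gave -1.73 for alveolar type 2 genes in epithelial-like cells. Sprouting endothelial genes in alveolar type 2-like cells (-0.94 as reported, 0.97 with members at 0 set to 3 UMIs) turned to 0.55 without doublets, 0.46 with marker sums and 0.71 with members of 1 UMI. The median log2 ratio of genes with 50 UMIs was -0.10 in mesenchymal-like and 0.16 in alveolar type 2-like cells; with it put at 0, matrix genes in mesenchymal-like cells had 0.62. As a mean over cells, interferon genes in all cells had 0.89 and alveolar type 2 genes in epithelial-like cells -2.11; thinned, they had 0.84 and -2.07, and endoplasmic reticulum stress genes in endothelial-like cells -0.0425.

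Without low-Malat1 cells, the niche shares were 3.05% epithelial-like and 39.0% endothelial-like. Medians in epithelial-like cells were then -0.53 for alveolar type 2, 0.0801 for alveolar type 1, 0.0911 for MHC class II and 0.10 for immediate early genes, and cell cycle genes in all cells had -0.0263. Without the mixed epithelial cluster, epithelial-like medians were -0.0636 for alveolar type 2, 0.72 for alveolar type 1, 0.57 for MHC class II and 0.0235 for lipid synthesis genes, and Scgb1a1, Vim and Phgdh had -0.19, -0.0165 and -0.54. Without the mesenchymal-like cluster led by Cxcl9 and Timp1, interferon genes in mesenchymal-like cells had 1.39. Within both UMI limits, the distal shares were 15.7% epithelial-like and 61.1% endothelial-like, interferon genes had 0.90 in all and 0.33 in endothelial-like cells, and matrix genes 0.38 in mesenchymal-like cells.

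Requiring 5 cell cycle UMIs gave, for niche and distal, 11.4% and 9.70% of all, 46.9% and 1.60% of epithelial-like, 11.5% and 13.8% of endothelial-like and 6.66% and 3.69% of mesenchymal-like cells. Unthinned shares were 77.4% and 63.6%, 84.4% and 77.6%, 81.5% and 65.3%, and 74.9% and 49.7% in the same order. Without low-Malat1 cells the niche epithelial-like share was 26.3%, and without the mixed epithelial cluster 20%.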

Other observations

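The test in this part was chosen only after the result had been seen. Some genes were listed in 1 table only. In niche mesenchymal-like cells the follistatin gene Fst had 762 UMIs, the chemokine gene Ccl5 988, the osteopontin gene Spp1 394 and the cytokine gene Lif 220. Niche epithelial-like cells carried 516 UMIs of S100a4, 81 of the mitotic gene Ube2c, 72 of the survivin gene Birc5 and 45 of Krt14, of which 465, 66, 66 and 42 lay in the 54 low-Malat1 cells of the mixed epithelial cluster. In endothelial-like cells of the niche, the lymphatic genes Mmrn1 (175 UMIs), Reln (44) and Prox1 (42) were listed, and Ptx3 had 117. The lymphatic-like cluster held 34 niche and 11 distal cells, and every gene listed for the distal library was detected in at least 11 cells. The listing of lymphatic genes can therefore follow the number of such cells. The distal table alone listed Retnla (891 UMIs) and the chitinase gene Chia1 (400) in epithelial-like cells. No ratio can be given for these genes.

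Transcripts of alveolar type 2 cells were lower in niche endothelial-like and mesenchymal-like cells than in distal ones. Free RNA from alveolar type 2 cells may be the source: the median level of these genes was 0.193% of the alveolar type 2-like level in niche and 0.856% in distal endothelial-like cells, and 0.0926% and 1.21% in mesenchymal-like cells. Of 44 values of abundant alveolar type 2 genes in these classes, 34 lay within 2-fold of the common share of their class and library: 9 of 10 in each distal class, and 8 of 12 in each niche class, short of the 80% that had been set as needed in each. For the niche, free RNA cannot be told apart from other sources by this test, while the distal values met that mark. The club cell gene Scgb1a1 went the other way, with 475, 795 and 525 CPM in niche endothelial-like, mesenchymal-like and immune-like cells against 118, 122 and 109 in distal ones.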
